A study of Neurospora crassa with 6 samples.

How the data were processed

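Polyadenylated RNA was sequenced from hyphae of a Neurospora crassa strain labelled as deleted for cry, vvd and wc-1 in 6 libraries, 2 each in darkness, at 1000 lux and at 5000 lux. Per the labels' protocols, hyphae were moved from minimal slants to medium with 2% glucose for 45 min under these conditions, RNA was taken with TRIzol and treated with DNase I, and Illumina libraries were made. The authors deposited 1 table of RPKM values with a column per library, and the submitters' processing notes list CASAVA 1.8 and HISAT without a version and without their roles. The genome build, the annotation, the counting tool and its strand setting are not given in the sources used here. The table holds 10559 genes, of which 10526 were matched by locus tag or symbol to a reference gene table of the NC12 assembly, used only for symbols, gene types and overlaps, and 33 were not matched. In that reference 2511 of the table's genes overlap another gene.

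The depth of each library was recovered from the steps between the deposited RPKM values, which are whole multiples of a step for each gene. Within 0.005 reads plus a relative 3e-07, 9772 of the 9773 genes above 0 in any library came out as whole reads in all libraries. The gene length found this way is the smallest that gives whole reads, and for the 1289 genes with under 20 reads in any library it is ambiguous, so the main fits used the RPKM values and not the recovered reads. The denominators of the RPKM came to 22540000 and 28260000 reads in darkness, 22810000 and 25930000 at 1000 lux, and 25950000 and 21420000 at 5000 lux, with 76.52% to 77.12% of them on genes. In a gene of 2000 bp, 3 reads equal 0.0531 to 0.07 RPKM, a floor that covers counting error only.

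Genes with at least 1 RPKM in at least 2 libraries were tested, 7841 in all, with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with an intensity trend of the variance and all 3 groups in 1 fit (residual degrees of freedom 3, prior 6.87). Each of the 3 comparisons used the Benjamini-Hochberg adjustment over all genes tested and an adjusted p under 0.05. The raw count methods named as alternatives in the plan were not run, because the table used holds RPKM only. Fold changes are on the log2 scale and rest on the pseudocount of 1 RPKM. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

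The tests, the samples in each fit, the rule for named genes, the alternatives and 28 gene lists were fixed before the data were examined. The rule takes wc-1, vvd and cry and the remaining photoreceptor and clock genes in every comparison, then per comparison the 10 genes with the largest increase and the 10 with the largest decrease among called genes with non-overlapping replicates and a symbol or product, and in each list up to 4 members with the smallest adjusted p. Of the 28 lists, 13 were given by locus tag and tested; of 15 given by product text, 12 had 0 members and 3 had 1, because the table and the reference hold almost no product text. A member, ccg-4, was dropped because the reference gives that symbol to another locus tag. 3 members carry another symbol in the reference (sor-4, emp-7 and ace-8) and were kept; none of the 3 was called in any comparison. After the gene names and the most changed genes had been seen, 12 lists by the start of the gene symbol were added. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted within each comparison separately over the 13 lists and the 12 lists, and again with an estimated correlation, which ended every camera call; fry was also run.

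The analysis was tested on simulated data for 1000 lux against dark over 7778 genes with 1 common SD of 0.111, so it describes genes of typical spread. Of genes changed by 1.5-fold, 84 of 99 were recovered (84.8%), and of genes changed by 2-fold, 97 of 100 (97%). Among 7579 unchanged genes 17 were called, more than 5% of the simulated calls. Of 200 lists without a change, 4 had camera p under 0.05. Those lists were random genes with noise drawn independently for each gene, so they lack the correlation between genes of a real list. For the real lists the estimated correlation ranged from -0.402 to 0.84. The simulation therefore does not check the camera calls of the real lists.

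Alternatives were other pseudocounts (0.1 and 5), other low-value filters, other scalings, no variance trend, library weights, only the groups compared, a block for the replicate number, and leaving out each library in turn, where the lone library of a group is assumed to vary like the others. 3 were added after the data had been seen: limma voom on the recovered reads, robust variance estimates, and protein-coding genes only. No separate test of outlying libraries was run, and the libraries were not regrouped at random.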

Results

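Polyadenylated RNA was sequenced from hyphae of a Neurospora crassa strain labelled as deleted for cry, vvd and wc-1, which encode the cryptochrome, the blue-light photoreceptor VIVID and the blue-light photoreceptor and transcription factor White Collar-1. Hyphae were grown for 45 min in medium with 2% glucose in darkness, at 1000 lux or at 5000 lux, and each of the 3 conditions has 2 libraries. The values are RPKM (reads scaled by gene length and library depth) for 10559 genes. Reads on genes, recovered from the steps between these values and rounded, came to 17300000 and 21620000 in darkness, 17590000 and 19850000 at 1000 lux, and 19950000 and 16450000 at 5000 lux. At these depths 1 read in a gene of 2000 bp equals 0.0177 to 0.0233 RPKM, counting error only. The labels do not say that the 2 libraries of a condition came from separate cultures, so the p-values measure only the spread between these samples.

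The genes labelled as deleted were not at 0 in any library. wc-1 (NCU02356) had 8.41 ± 0.888 RPKM in darkness, 7.17 ± 0.297 at 1000 lux and 6.63 ± 0.453 at 5000 lux (mean ± SD, n = 2, as for all such values here). vvd (NCU03967) had 3.33 ± 0.16, 2.05 ± 0.138 and 2.59 ± 0.16 RPKM in the same order, and cry (NCU00582) had 2.18 ± 0.00754, 2.08 ± 0.684 and 2.12 ± 0.00436. The median over all 10559 genes was 7.49 to 8.241 RPKM in the 6 libraries, so wc-1 lay near the median gene and vvd and cry below it. The series has no strain carrying these genes intact, and a value per gene does not show which part of a gene its reads cover. The values of the 3 genes therefore do not check the labels. cry also overlaps NCU00583, and reads of overlapping genes cannot be told apart here because the counting and its strand setting are not given in the sources used. Of the 3 genes, vvd alone passed the test in any comparison, at 1000 lux against dark, where its log2 fold change was -0.51 (SE 0.15, limma adjusted p = 0.0473); that call was lost without each of the 6 libraries in turn, where the log2 fold change ranged from -0.55 to -0.46.

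The first comparison asks which transcripts differ between 1000 lux and darkness in the strain labelled as deleted for these 3 photoreceptor genes. Several genes of the cell wall and the clock-controlled gene ccg-13 were higher at 1000 lux. Some, but not all, of the tested genes of gluconeogenesis, acetate use and amino acid synthesis were lower. ncw-5 (NCU00716), a non-anchored cell wall protein gene, went from 43.7 ± 5.88 to 212 ± 38.8 RPKM, and ccg-13 (NCU08907) from 594 ± 87.3 to 2509 ± 393 RPKM, log2 fold changes of 2.25 (SE 0.15) and 2.08 (SE 0.13) with limma adjusted p = 4.637e-05 each. acu-6 (NCU09873), which encodes phosphoenolpyruvate carboxykinase, went from 37.4 ± 0.611 to 8.53 ± 1.01 RPKM (-2.02, SE 0.12, limma adjusted p = 4.637e-05). aod-1 (NCU07953), the alternative oxidase, went from 24.7 ± 1.51 to 8.96 ± 0.384 RPKM (-1.37, SE 0.1, limma adjusted p = 6.439e-05). ncw-5 overlaps NCU00715, so the reads of this pair cannot be told apart.

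Across the 7841 genes tested, 716 were higher and 613 lower at 1000 lux than in darkness at a limma adjusted p under 0.05, 48 and 38 of them by at least 2-fold. Among all 7841 genes tested, called or not, the replicates of the 2 conditions did not overlap in 4613 (58.8%), where chance gives 33.3%. Other large increases were in gh28-1 (NCU02369, overlapping NCU02368), lyz (NCU00701) and asd-1 (NCU05598), a gene of ascus development, with log2 fold changes of 1.43, 1.26 and 1.23. eas (NCU08457), which encodes the hydrophobin of the conidial surface, was lower at -1.38, from 193 ± 27.5 to 73.3 ± 3.93 RPKM. Without 1000 lux replicate 1 the counts were 239 higher and 186 lower, without 1000 lux replicate 2 they were 501 and 384, and without dark replicate 1 they were 663 and 367; the direction of more calls turned without dark replicate 2, at 517 higher and 623 lower.

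Among the 12 tested genes of the list of glycolysis, fermentation and gluconeogenesis, 5 were lower at 1000 lux than in darkness and 0 were higher, and adjusted over the list alone the counts were again 5 and 0. The camera test of this list gave adjusted p = 0.0003624, and adjusted p = 0.768 with an estimated correlation. The 5 genes were acu-6, aod-1, acu-3 (isocitrate lyase) at -1.12, acu-9 (malate synthase) at -0.93 and adh-1 (an alcohol dehydrogenase gene, overlapping NCU01753) at -0.62. acu-6, acu-3 and acu-9 belong to gluconeogenesis and acetate use, aod-1 to respiration and adh-1 to fermentation, so none is an enzyme of glycolysis. The count stayed at 5 without each library in turn.

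The light-induced and conidiation lists had calls in both directions at 1000 lux. Of 15 tested genes known to be induced by light in wild type, 3 were higher (ccg-1, bli-3 and con-10 at 0.62, 0.62 and 0.96) and 2 were lower (al-2 and al-1, which encode phytoene synthase and phytoene desaturase of carotenoid synthesis, at -0.33 and -0.62), and adjusted over the list alone the counts were also 3 and 2. The list's median log2 fold change was -0.077 and its mean 0.007, with the camera test pointing down (adjusted p = 0.9004, and adjusted p = 0.9787 with an estimated correlation). Of 5 tested carotenoid synthesis genes, al-2 and al-1 made 2 lower and 0 were higher, the same counts adjusted over the list alone (camera adjusted p = 0.3179, and adjusted p = 0.8716 with an estimated correlation). Of 10 tested conidiation genes, 2 were higher (ccg-1 and con-10) and 2 lower (eas and acon-2), the same counts adjusted over the list alone. The con-10 call was lost without dark replicate 2, where its log2 fold change was 0.67, and without either 1000 lux library. The al-2 call was kept only without dark replicate 2 and the al-1 call only without 1000 lux replicate 2. acon-2 was lost without every library in turn, with log2 fold changes from -0.59 to -0.44.

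Of the 9 remaining photoreceptor and clock genes, 8 were tested and phy-2 (NCU05790) lay below the minimum at 0.528 ± 0.155, 0.221 ± 0.0297 and 0.231 ± 0.0313 RPKM. The members were listed beforehand by locus tag, and their functions were not checked here. NCU01735, which has no symbol in the reference table, went from 96.0 ± 7.18 RPKM in darkness to 54.8 ± 0.792 at 1000 lux and 50.9 ± 4.26 at 5000 lux (log2 fold changes -0.80 and -0.90, SE 0.09 each, limma adjusted p = 0.0007871 and 0.001429), and both calls were kept without each library in turn. At 1000 lux frh (NCU03363), the FRQ-interacting RNA helicase, was higher (0.41), the opsin gene nop-1 (NCU10055) was higher (0.70) and fwd-1 (NCU04540, overlapping NCU04541) was lower (-0.30). At 5000 lux frh was higher (0.49), a call lost without either 5000 lux library. Adjusted over the list alone, 3 were higher and 2 lower at 1000 lux, and 1 and 1 at 5000 lux. The frh call at 1000 lux was lost without dark replicate 1 or 1000 lux replicate 1, the nop-1 call without either dark or either 1000 lux library, and the fwd-1 call without each of the 6. The clock gene frq (NCU02265) had 4.98 ± 1.25, 4.61 ± 0.337 and 5.57 ± 0.109 RPKM and wc-2 (NCU00902), the partner of White Collar-1, had 39.3 ± 0.481, 46.2 ± 1.01 and 44.9 ± 4.02 RPKM in darkness, 1000 lux and 5000 lux; neither passed the test. Between 5000 and 1000 lux 0 of the 8 passed limma or voom at adjusted p under 0.05, and 1 had an unadjusted p under 0.05.

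A further 12 lists were formed from gene symbols after the most changed genes had been seen, so their counts are not independent evidence of a direction. Of 53 genes with symbols of amino acid synthesis, 25 were lower and 4 higher at 1000 lux than in darkness. Among them were his-6 (-1.13), arg-10 (-1.04), arg-5 (-0.92), aro-1 (-0.88) and trp-3 (-0.88) on the lower side. On the higher side were leu-2 (0.65) and cys-11 (0.51), and the remaining higher calls also had cys symbols. his-6, trp-3 and leu-2 overlap NCU07155, NCU16588 and NCU04386. The camera test gave adjusted p = 2.472e-07, and adjusted p = 0.4624 with an estimated correlation; without 1000 lux replicate 1 the lower count was 14. Of 26 cell wall symbols, 8 were higher and 1 lower, with ncw-5, ncw-3 (0.94), ncw-6 (0.71) and acw-12 (0.58, overlapping NCU08172) among the higher ones (camera adjusted p = 0.048, and adjusted p = 0.7205 with an estimated correlation), and this list call was lost under quantile normalization at camera adjusted p = 0.08825. The 1 lower call was lost without either dark or either 1000 lux library. Of 6 acetate utilization symbols, 4 were lower (camera adjusted p = 0.0001425, and adjusted p = 0.4624 with an estimated correlation). Among them acu-6, acu-3 and acu-9 were already counted in the list of glycolysis, fermentation and gluconeogenesis.

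**Figure D1:**
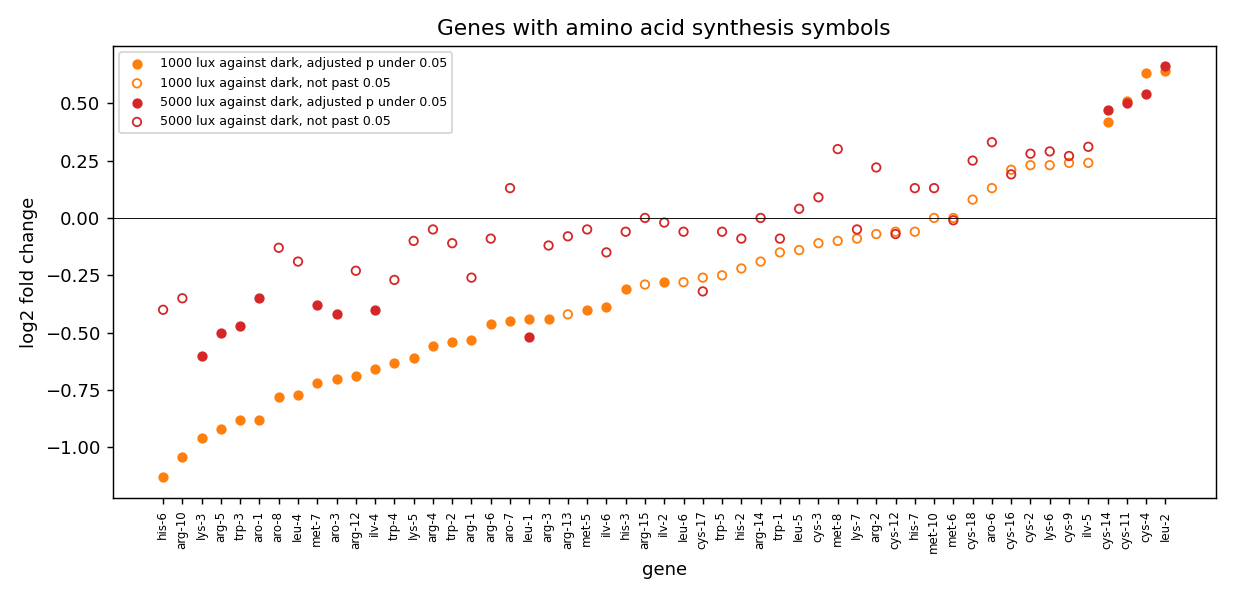
Log2 fold change (vertical axis) of the 53 genes with symbols of amino acid synthesis at 1000 lux and at 5000 lux against darkness, ordered by the value at 1000 lux, with filled points for a limma adjusted p under 0.05. At 1000 lux 25 genes are lower and 4 higher, and at 5000 lux 8 are lower and 4 higher.

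The second comparison asks which transcripts differ between 5000 lux and darkness. ncw-5 at 108 ± 17.4 RPKM and ccg-13 at 1335 ± 142 RPKM were again higher than in darkness, with log2 fold changes of 1.28 (SE 0.15, limma adjusted p = 0.001507) and 1.17 (SE 0.13, limma adjusted p = 0.001458). prm-3 (NCU01669, overlapping NCU01670) went from 9.99 ± 0.522 to 21.9 ± 0.925 RPKM (1.06), and prm-1 (NCU07459), mig-2 (NCU07452, overlapping NCU07453) and the zinc transporter gene tzn-1 (NCU07621) were higher at 0.94, 0.92 and 0.90. acu-6 at 12.6 ± 1.86 RPKM and aod-1 at 12.8 ± 0.513 RPKM were lower (-1.50 and -0.90). bli-3 (NCU07267, overlapping NCU07266) and ccg-1 (NCU03753) were higher at 0.80 and 0.74. All of these calls were kept without each library in turn.

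In total 525 genes were higher and 229 lower at 5000 lux than in darkness at a limma adjusted p under 0.05, 23 and 12 of them by at least 2-fold, so that 69.6% of the calls were higher. With median-of-ratios scaling 58.6% of the calls were higher, and with quantile normalization 57.2%. The counts were 104 higher and 38 lower without 5000 lux replicate 1, 196 and 53 without 5000 lux replicate 2, 527 and 141 without dark replicate 1, and 369 and 230 without dark replicate 2. Of the 46 called genes named under the rule, 13 kept their call without each library in turn, among them leu-2 and the kinase gene stk-52 at 0.66 and 0.71.

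In the list of glycolysis, fermentation and gluconeogenesis 3 of 12 genes were lower at 5000 lux (acu-6, aod-1 and adh-1) and 0 were higher, with 4 lower adjusted over the list alone (camera adjusted p = 2.634e-05, and adjusted p = 0.5654 with an estimated correlation). The adh-1 call, at -0.51, was lost without 5000 lux replicate 2, which leaves 2. Of the 15 light-induced genes, bli-3, ccg-1 and al-2 (0.39) were higher and 0 were lower, with 4 higher adjusted over the list alone (camera adjusted p = 0.2729). The al-2 call was lost without dark replicate 2 and without either 5000 lux library, and 5 of this list were higher without dark replicate 1, while 1 was lower without dark replicate 2. The heat shock gene hsp80 (NCU04142) was lower at both intensities, at -0.49 and -0.50, and its call at 5000 lux was lost without 5000 lux replicate 1. Of 53 amino acid synthesis symbols, 8 were lower and 4 higher (camera adjusted p = 0.2954), and the lower count was 0 without 5000 lux replicate 2, 3 without 5000 lux replicate 1 and 4 without dark replicate 2. The higher count was 1 without 5000 lux replicate 1 and 2 without dark replicate 1.

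**Figure D2:**
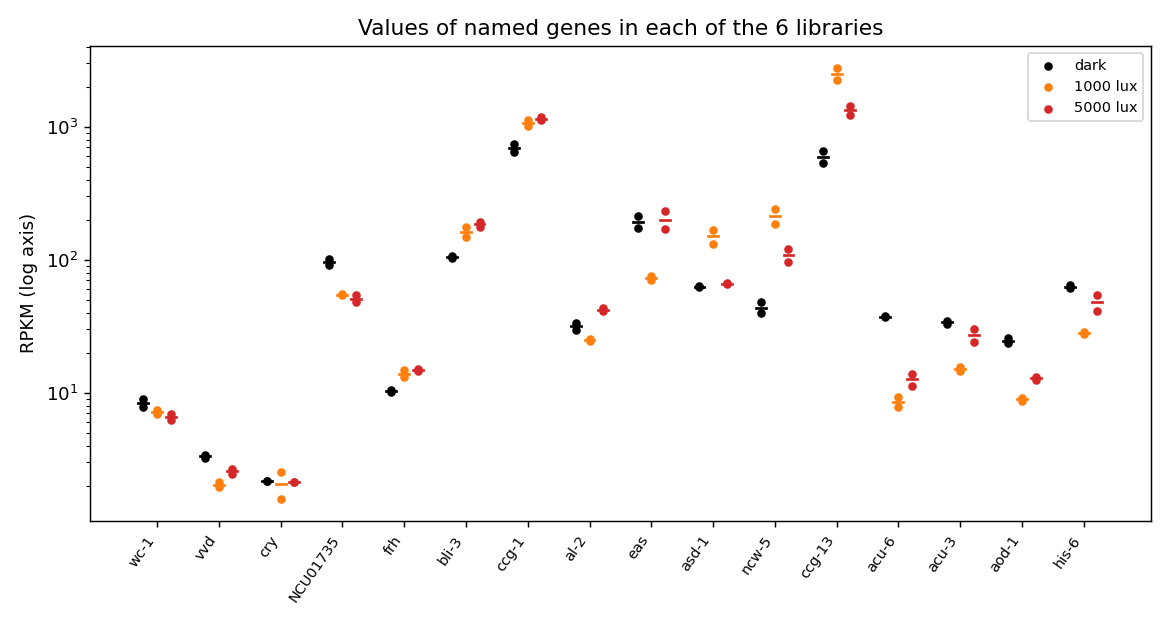
RPKM (vertical log axis) of 16 named genes in each library, with points for the 2 libraries of a condition, a bar for their mean, and black, orange and red for darkness, 1000 lux and 5000 lux. ncw-5 goes from a mean of 43.7 RPKM in darkness to 212 at 1000 lux and 108 at 5000 lux.

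Both light intensities were set against the same 2 dark libraries, so their chance values are shared. 377 genes were higher and 156 lower than darkness at both intensities, and 5 had opposite calls. Independent lists of these sizes would share 47.9 and 17.9 genes, but these lists share their dark libraries. In 100 simulations, noise was drawn afresh for all 6 libraries, with both unchanged light groups set against the same simulated dark group. The highest number called the same way at both was 0, which decides nothing because the adjustment leaves few calls without a change. The noise was independent between genes, so deviations that many genes of a library share are missing from the simulated values. Across genes, which are not independent replicates, the fold changes correlated at r = 0.716, against 0.504 in the simulations, and 76.3% had the same sign, against 66.7%. Their covariance was 0.0701 against a simulated 0.0135, a difference of 0.0567. With 2 dark libraries the controls could not be split with 2 in each part, so part of the excess may come from the shared controls. Without 5000 lux replicate 1 the shared counts were 94 and 32, without 5000 lux replicate 2 they were 167 and 36, without 1000 lux replicate 1 they were 162 and 75, and without dark replicate 1 the lower count was 96.

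**Figure D3:**
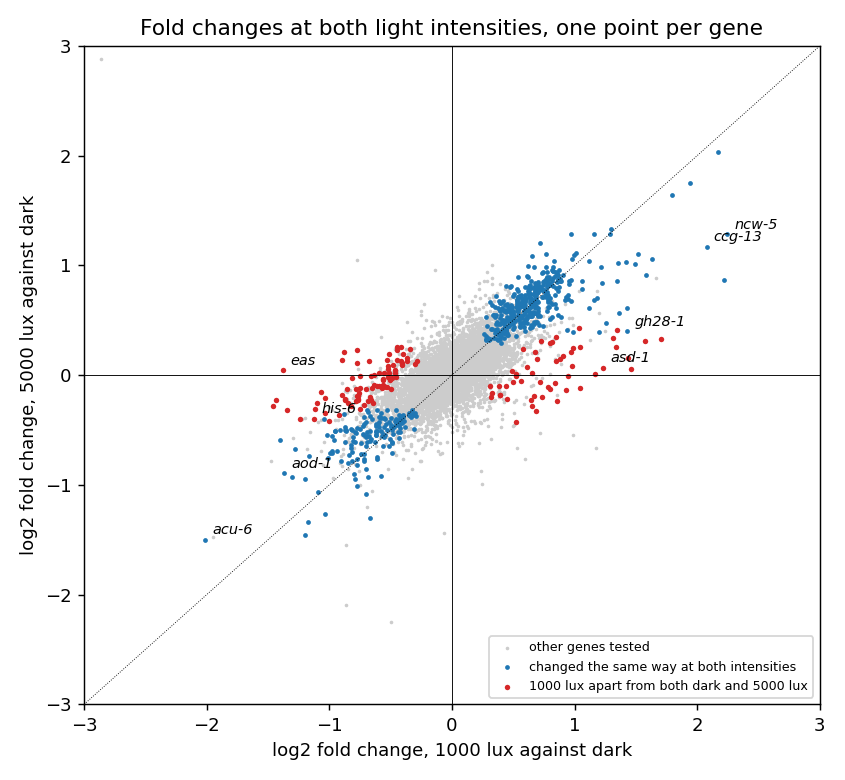
Log2 fold change of each gene at 1000 lux (horizontal axis) and 5000 lux (vertical axis) against darkness, with 7840 genes drawn and 1 outside the axes. Blue points were called the same way at both intensities and red points were called at 1000 lux against both other conditions but not at 5000 lux against darkness; of the 377 genes called higher and the 156 called lower at both, 1 lower gene (NCU15731) lies outside the axes, and 53 red genes are higher and 83 lower at 1000 lux.

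The third comparison tests the difference between 5000 and 1000 lux itself. It shares the 2 libraries at 1000 lux with the first comparison, where they enter with the opposite sign. A chance or handling shift at 1000 lux would therefore appear in both, in opposite directions. Opposite results of a gene or list in these comparisons are not independent of each other. eas was at 200 ± 43.5 RPKM at 5000 lux, above 73.3 ± 3.93 at 1000 lux and near its 193 ± 27.5 in darkness (log2 fold change 1.42, SE 0.14, limma adjusted p = 0.001248). asd-1 was lower at 5000 lux, at 66.1 ± 1.04 RPKM against 150 ± 25.2 at 1000 lux (-1.16, SE 0.11, limma adjusted p = 0.0008377), as were gh28-1 (-1.03) and lyz (-0.79). These 4 were the only called genes named under the rule, of 31, that kept their call without each library in turn. ncw-5 and ccg-13 were lower at 5000 than at 1000 lux, at -0.96 and -0.90; the ncw-5 call was lost without 1000 lux replicate 2 or 5000 lux replicate 2, and the ccg-13 call without 1000 lux replicate 2. acu-3 was higher at 0.81, lost without 1000 lux replicate 1 or 5000 lux replicate 1.

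In total 130 genes were higher and 107 lower at 5000 than at 1000 lux at a limma adjusted p under 0.05, 7 and 19 of them by at least 2-fold. With median-of-ratios scaling the direction of more calls turned, at 138 higher and 150 lower. The counts fell without each light library in turn and rose without either dark library. A fit without a light library leaves 1 in its group and so has less power, which cannot be told apart from dependence on that library. These fits share libraries with the main fit, and their fold changes correlated with it at 0.904 to 0.927. With only the 2 groups compared the counts were 204 and 137. Of the genes changed at 1000 lux against darkness, 53 higher and 83 lower ones were also called between 1000 and 5000 lux in the same direction and not called at 5000 lux against darkness; without 5000 lux replicate 1 these were 15 and 1, without 1000 lux replicate 1 they were 16 and 4, without 1000 lux replicate 2 they were 20 and 16, without 5000 lux replicate 2 they were 40 and 55, and without dark replicate 2 they were 64 and 132.

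Of the 53 amino acid synthesis symbols, 11 were higher and 0 lower at 5000 than at 1000 lux, among them his-6 (0.73), arg-10 (0.69), leu-4 (0.57) and aro-1 (0.53), with camera adjusted p = 2.344e-12 and adjusted p = 0.3344 with an estimated correlation. Without 1000 lux replicate 1, and likewise without 5000 lux replicate 1, 0 were higher; without 1000 lux replicate 2 there were 2 and without 5000 lux replicate 2 there were 7. Of the 26 cell wall symbols 6 were lower and 0 higher, among them ncw-4 (-0.54), gel-4 (-0.61) and ncw-3 (-0.53), with camera adjusted p = 0.0006687 and adjusted p = 0.4892 with an estimated correlation. Without 1000 lux replicate 2 the cell wall count was 0, without 5000 lux replicate 1 it was 1, and without 1000 lux replicate 1 or 5000 lux replicate 2 it was 2. Of the 6 acetate utilization symbols 2 were higher, acu-3 and acu-15 (0.58), with camera adjusted p = 6.768e-05 and adjusted p = 0.3344 with an estimated correlation, and 0 were higher without 1000 lux replicate 1 or 5000 lux replicate 1, 1 without 1000 lux replicate 2 or 5000 lux replicate 2, and 4 without dark replicate 1 or 2.

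Of the 13 lists fixed beforehand and tested, 6 passed the camera test between the intensities, each with adjusted p = 0.6283 with an estimated correlation. Some of them share members. All 5 carotenoid genes are also in the light-induced list, and con-10, csp-1 and ccg-1 are in both the light-induced and the conidiation list. The passes of these lists are therefore not separate. The antioxidant list pointed down (camera adjusted p = 0.02882) with 1 of 6 genes called, sod-2 at -0.53, and 2 lower adjusted over the list alone. The glucose uptake list pointed up (camera adjusted p = 0.03783) with 1 of 5 called, NCU01633 at 0.57, and 3 higher adjusted over the list alone. The light-induced, carotenoid, conidiation and histone lists pointed up (camera adjusted p = 0.04435 each). Of these, al-2 (0.72) was the 1 gene called in the first and second, with 3 and 1 higher adjusted over the list alone. Of the conidiation genes eas and rca-1 (0.51) were higher and con-8 (-0.96) lower, with 4 higher and 1 lower adjusted over the list alone, and 0 of 5 histone genes passed limma or voom, with 1 at an unadjusted p under 0.05. The sod-2, NCU01633 and con-8 calls were lost without either 1000 lux library or 5000 lux replicate 1, the al-2 call without 1000 lux replicate 1 or 5000 lux replicate 1, and the rca-1 call without any 1 of the 4 light libraries. The histone list call was lost with median-of-ratios scaling, at camera adjusted p = 0.08521.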

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

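Chosen only after the results had been seen were the voom, robust and protein-coding alternatives, the 12 lists by symbol, and the set of genes counted next. For called genes and the deleted, photoreceptor and clock genes, 2681 of 3098 alternative values kept direction and side of the threshold, 405 were weaker and 12 reversed. This set was narrowed after the wider count was seen: over all genes the naming rule takes, called or not, 59 of 6169 values reversed, in 25 genes, all with a main log2 fold change of at most 0.19 in size and none of them called. For lists, 1341 of 1419 values stayed the same, 70 were weaker and 8 stronger. A list that passed camera in neither fit was counted as the same whatever its direction. The total therefore says little about the lists that passed. Of the weaker values, 47 were of planned lists between the intensities, where 197 stayed the same. For each setting below the cause was not tested.

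Leaving out 1 library in turn moved the counts most. Such a fit has 1 library in a group and so less power, which the counts cannot separate from dependence on that library. At 1000 lux against dark the higher count ranged from 239 to 663 and the lower from 186 to 623. At 5000 lux against dark they ranged from 104 to 527 and from 38 to 230, and between the intensities from 1 to 214 and from 18 to 141. Genes called in both a main and a left-out analysis had the same direction. Among genes not called, the log2 fold change at 1000 lux against dark ranged from -0.3 to 0.16 for cry, -0.29 to 0.14 for frq, -0.15 to 0.14 for phy-1 and -0.04 to 0.02 for ck-1a. At 5000 lux against dark it ranged from -0.06 to 0.37 for frq and -0.03 to 0.25 for phy-1, and between the intensities from -0.19 to 0.27 for cry and -0.13 to 0.05 for wc-2. The voom alternative gave 0.01 for phy-1 at 1000 lux, and quantile normalization 0.01 for cry at 5000 lux against dark.

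At 5000 lux against dark no low-value filter gave 340 higher and 123 lower, no variance trend 337 and 142, and both median-of-ratios scaling and quantile normalization gave 371 lower. Between the intensities no filter gave 42 and 47, no trend 15 and 27, array weights 222 and 165, only the 2 groups compared 204 higher, and voom 202 higher. The correlation and covariance of the fold changes at both intensities were 0.729 and 0.0684 with at least 5 RPKM in 2 libraries. With median-of-ratios scaling cry had 2.2 RPKM in darkness and 2.09 at 5000 lux.

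The number of planned lists passing camera was 0 in each comparison with an estimated correlation. The directional fry test passed 0 at 5000 lux against dark and 0 between the intensities, and the mixed fry test passed 10 at 1000 lux and 11 at 5000 lux against dark. Without 1 library in turn the number ranged from 1 to 2 at 1000 lux, from 1 to 2 at 5000 lux, and from 0 to 5 between the intensities. Between the intensities it was 2 with a pseudocount of 5, 3 with at least 5 RPKM, 1 with only the 2 groups compared, 2 with no variance trend and 2 with array weights.

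The replicate numbers share only a number: the deviations of same-numbered libraries correlated at 0.028, -0.087 and 0.052, and there are only 2 numbers. With the replicate block the counts were 737 higher and 606 lower at 1000 lux, 558 and 236 at 5000 lux, and 130 and 108 between the intensities.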

Other observations

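Of the tests here, the one on the numbers in the sample titles and the one on counting error were chosen only after the result was seen; the 12 lists by symbol and the single genes named by locus tag alone were chosen after their values were seen, and the 3 patterns were found in these data.

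Other lists fixed beforehand held few calls. Among 7 heat shock genes, 3 were lower at 1000 lux (hsp80, hsp60 and hsp30) with 4 adjusted over the list alone, and 2 at 5000 lux, hsp80 and hsp30, with 2 lower and 1 higher adjusted over the list alone; hsp80 was the 1 kept without each library in turn at 1000 lux. The hsp30 call at 5000 lux was lost without either dark or either 5000 lux library. Without each library in turn its log2 fold change ranged from -0.55 to -0.5. The camera tests of this list gave adjusted p = 0.09048 and 0.0702. At 1000 lux sod-2 (0.52) and cat-1 (0.29) were the antioxidant genes called, with 2 higher adjusted over the list alone, and cat-1 was lost without each library in turn. asd-1 was the 1 of 7 sexual development genes called at 1000 lux, with 2 adjusted over the list alone, and Asm-1 (0.40) the 1 at 5000 lux, lost without either 5000 lux library. The cellobiose transporter gene cdt-1 (NCU00801, overlapping NCU10770) was higher at both intensities (0.57 and 0.70), the 1 of 4 tested cellulose response genes called; the call was lost at 1000 lux without 1000 lux replicate 1 and at 5000 lux without either 5000 lux library. nuc-1 (-0.37) was the 1 of 5 nitrate and phosphate genes called at 1000 lux, and was kept only without dark replicate 2, where 3 of that list were lower. The linker histone gene hH1 (0.28) was the 1 of 5 histone genes called at 5000 lux, lost without each library in turn, and cyp450-31 (-0.89), the 1 member of the cytochrome P450 list, was called at 1000 lux and kept only without dark replicate 1.

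Among the lists by symbol, 29 complex I genes had 3 higher at 1000 lux (nuo9.8, nuo21.3c and nuo21.3b), camera adjusted p = 0.0003162, and adjusted p = 0.4624 with an estimated correlation, with 0 without 1000 lux replicate 1. Between the intensities the same list pointed down (camera adjusted p = 5.341e-05, and adjusted p = 0.3344 with an estimated correlation) with 0 genes called by limma or voom and 3 at an unadjusted p under 0.05. Of 21 mitochondrial import genes 4 were higher at 1000 lux (camera adjusted p = 0.04704, and adjusted p = 0.7205 with an estimated correlation), 0 without 1000 lux replicate 1. Of 59 protein kinase genes 7 were lower and 1 higher at 1000 lux (camera adjusted p = 0.04812, and adjusted p = 0.7205 with an estimated correlation), with 3 lower without either 1000 lux library; this list call was lost with quantile normalization at camera adjusted p = 0.06051. Of 52 glycoside hydrolase genes 4 were higher and 4 lower at 1000 lux, with 0 lower without 1000 lux replicate 1. Of 12 genes with heat shock symbols 2 were higher, hsp20_family (1.35) and hsp30-like_protein (0.85), and 4 lower, with 1 lower without either 1000 lux library. rpn-4 (-0.81) was the 1 of 30 proteasome symbols called at 1000 lux. The peroxisome, vacuolar ATPase and DNA repair lists had 0 genes called by limma or voom in any comparison; at an unadjusted p under 0.05 there were 0, 4 and 3 at 1000 lux, 0, 1 and 5 at 5000 lux, and 0, 0 and 4 between the intensities.

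Several of the largest changes were in genes that have no symbol. NCU00399, which overlaps NCU00398, had 306 ± 13.8 RPKM in darkness, 1428 ± 65.1 at 1000 lux and 559 ± 28.2 at 5000 lux. NCU05512 and NCU17100, which overlap each other, were higher at both intensities (2.17 and 2.03 for NCU05512, 1.94 and 1.75 for NCU17100). NCU10865 and NCU00732 were lower at 5000 than at 1000 lux (-1.85 and -1.54). NCU15731, annotated as ribosomal RNA and overlapping other genes, had 42.0 and 75.2 RPKM in the dark libraries, 1.64 and 26.3 at 1000 lux, and 0.117 and 0.0706 at 5000 lux.

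Dark replicate 2 had more reads than the other libraries at 1518 genes that were nearly silent in replicate 1 of both light groups. With reads thinned to equal totals it had 5787 against 2631 in dark replicate 1, a ratio of 2.2, which argues against deeper sequencing as the source. For 851 silent protein-coding genes that overlap no other gene, reads were estimated from the RPKM over the full gene span. These estimates varied 14 times as much as Poisson reads spread evenly by gene length. Of these genes 367 had no read where 20 were expected, which argues against evenly spread DNA as the whole source. Where the counted length is shorter than the span, the estimates are too high. This raises the ratio and lowers the expected number by an amount that was not measured. Darkness as a cause stays open, since dark replicate 1 had 1.48 times the reads of the higher held-out light library, just under the 1.5 set for it. Its 2631 reads stood against 1774 in 1000 lux replicate 2 and 754 in 5000 lux replicate 2.

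Several readings are possible for the genes that differed at 1000 lux from both other conditions (53 higher and 83 lower). They may reflect a response limited to that intensity, a response that is weaker at 5000 lux, or a difference in how those cultures were handled. They were not called at 5000 lux against darkness, which does not show that they were unchanged there. In that comparison his-6 had a log2 fold change of -0.40 and asd-1 of 0.07. Of 201 genes chosen in replicate 1 as at least 1.5-fold apart from both, 77.1% lay on the same side in replicate 2. Of 102 chosen in replicate 2, 84.3% did in replicate 1. Chance gives 33.3% for a gene equal in all 3 conditions, and more for a gene changed alike at both intensities. These shares argue against chance in 1 library for the genes chosen this way, which need not be the 53 and 83 called ones. The share of the 136 genes with a mean under 5 RPKM, 5.1% against 20.7% of all genes tested, decides nothing because the low-value filter and the choice of called genes remove low genes beforehand. In 134 of them (98.5%), against 14.7% of all genes tested, both differences were over 5 times the Poisson counting error of the recovered reads. The genes were chosen by these same differences, which raises the share. Counting error alone would still put hardly any of 7841 genes that far apart. The fewest reads of a pattern gene in any library had a median of 1253.5. These values argue against low reads or counting error as the whole source in those 134 genes. As a part of the differences, and in the remaining pattern genes, both stay open. Passing this bound does not separate a difference between conditions from spread between libraries. The 2 libraries of a condition also differed beyond counting error, over genes with at least 20 reads in both together. Chi-square per degree of freedom was 21.83 in darkness, 28.45 at 1000 lux and 12.52 at 5000 lux. An order of culture or handling cannot be told apart from light: the numbers in the sample titles are 1 and 2 in darkness, 5 and 6 at 5000 lux, and 10 and 12 at 1000 lux, with 0 pairs of groups overlapping, and the first principal component has means of 0.55, -0.16 and -0.4 in that order. What these title numbers stand for is not stated.

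A candidate explanation for the lower amino acid synthesis genes at 1000 lux is a lower message of cpc-1 (NCU04050), the activator of cross-pathway control of these genes. cpc-1 was lower at 1000 lux, at -0.44 (SE 0.09, limma adjusted p = 0.01065), which is consistent with this. The call was lost without 1000 lux replicate 1 (adjusted p = 0.1064; 0.01471 to 0.04787 without each of the others). Between the intensities cpc-1 changed by 0.13 (limma adjusted p = 0.5605) while 11 of the genes were higher, a count that was 0 without 1000 lux replicate 1 or 5000 lux replicate 1 and 2 without 1000 lux replicate 2, so whether its message follows that rise stays open. A shared cause of both, such as the handling order above, was not tested.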
